A study of Homo sapiens with 6 samples.

How the data were processed

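The 6 libraries fall into a control siRNA group and a HOTAIR-N siRNA group by their labels, with 3 libraries each that the series' design text describes as independent transfections. Per the labels' protocols, T47D cells were grown in RPMI medium with 10% serum and transfected with a lipid reagent, RNA was extracted after 48 hours, ribosomal RNA was removed and stranded total RNA libraries were made and sequenced on an Illumina instrument. STAR 2.6.0c, RSEM 1.3.0 and the genome build hg19 are named in the submitters' processing notes, without their settings. Whether the counting used strand is not given in the sources used here, so genes that overlap on opposite strands are treated as uncertain.

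Each library has 2 tables. Per the file headers, the gene tables and the transcript tables hold expected counts as RSEM estimates them, which need not be whole, and the deposited tables also give TPM and FPKM per gene or transcript. The share of each transcript within its gene is deposited as a percent in the transcript tables. The gene tables list 27968 genes by symbol, and 70006 RefSeq transcripts are in the transcript tables. The expected counts per library summed to 36707169, 35106084 and 35995047 in control siRNA replicates 1, 2 and 3 and to 35259407, 31777001 and 33362083 in those of the HOTAIR-N siRNA. EEF1A1, the most abundant gene, took at most 0.976% of the counts of a library. No pair of libraries of one group agreed within sampling noise (chi-square per degree of freedom of 2.21 or more), and all libraries were counted as separate replicates.

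Expected counts were rounded to whole numbers, filtered with edgeR's filterByExpr at its default settings (minimum count 10, minimum total count 15), scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) without covariates. Genes and transcripts were called at a Benjamini-Hochberg adjusted p under 0.05. CPM are TMM-scaled, and log2 fold changes are HOTAIR-N siRNA over control siRNA. Transcript usage was tested with edgeR's diffSpliceDGE, with a Simes p per gene. Of 27 gene lists, 26 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. The 9 calls were repeated with a correlation estimated from the 6 libraries, under which 0 lists were called (3 had an unadjusted p under 0.05), and with fry, which asks whether a list's genes move on balance one way and called 21, or change in either direction and called 26. Fry does not compare a list with the other genes, and 71.1% of tested genes changed, so its calls do not set a list apart from the rest. Members of each list were counted with adjustment over all genes and over the list alone.

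The tests, the lists and the rule for named genes were fixed before the data were examined. Named genes are HOTAIR, the 12 largest rises and 12 largest falls among called genes with an average log2 CPM of at least 0, no overlap between the groups and no small RNA, LOC, LINC or clone symbol, the 4 members of each list with the smallest p, and the 5 genes with the smallest Simes p. Some genes chosen by this rule are not printed. Members that went against their list, and KDM1A, were named after their values were seen. Further gene groups in the closing section come from 5 lists written after the data were examined.

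The steps were tested on simulated counts drawn from the means and library sizes of this comparison. Among 14919 genes with 200 planted changes, 48% of those changed 1.2-fold, 72% of those changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 16 genes without a planted change were called. In the data 71.1% of tested genes changed, and the adjusted p depends on that share, so the shares recovered may differ there. A planted list of 40 genes shifted 1.5-fold was called and 0 of 25 random lists were, with camera adjusted p. The simulated genes were drawn independently, whereas the correlation estimated in the data was 0.8 for the interferon-stimulated genes. The simulation therefore does not show how often camera calls a list falsely in the data. Among 32285 transcripts, a switch planted in 200 genes was recovered in 51.5% by the usage test, which also called 52 genes without one. A limma test of each transcript's log2 share of its gene, with its own variance, recovered 59.5% and called 8 without one.

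Alternatives planned before the data were examined were DESeq2 size factors, library totals alone or upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the replicate number as a block, each library left out, a test against a 1.2-fold change and stricter thresholds. For the closing section, the log2 fold change was regressed on the presence of each 7-mer, with UTR length and GC content as covariates. The 7-mers were those found in the 3′ UTRs of at least 100 genes. The scan covered 12849 tested genes (86.1%) with a 3′ UTR of at least 50 bases in GENCODE 29 (Python 3.11.15, numpy 2.4.6). In simulations with a 7-mer planted at a shift of -0.4, the planted 7-mer ranked first in 20 of 20. Coordinates are not given, since no hg19 genome was used here. Small RNAs were not measured by these libraries and the sequences of both siRNAs are not given in the sources used here.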

Results

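RNA was sequenced from T47D, a human estrogen receptor-positive luminal breast cancer cell line, after transfection of a control siRNA or of an siRNA described as specific for HOTAIR-N, a form of the long noncoding RNA HOTAIR. HOTAIR is transcribed from the HOXC cluster and has been linked to the chromatin repressor PRC2 and the demethylase LSD1. Each group held 3 libraries from independent transfections, and total RNA was taken 48 hours after transfection. The deposited gene tables summed to between 31777001 and 36707169 expected counts per library, so that 1 CPM stood for about 32 to 37 counts. The comparison asks how the transcriptome of these cells differs after the HOTAIR-N siRNA.

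HOTAIR itself was lower in all 3 libraries of the HOTAIR-N siRNA. Its expected counts were 577, 540 and 581 in control siRNA replicates 1, 2 and 3 and 206, 185 and 196 in the same replicates of the HOTAIR-N siRNA. The level was 16.3 ± 0.301 CPM (SD, n = 3) with the control siRNA and 5.65 ± 0.0242 CPM (SD, n = 3) with the HOTAIR-N siRNA, or 34.7% of control (log2 fold change -1.53, SE 0.07, edgeR quasi-likelihood adjusted p = 2.1e-09). HOTAIR overlaps HOXC11 on the opposite strand and the strand setting of the counting is not given in the sources used here, so that reads of HOXC11 could add to these values. The 3 annotated HOTAIR transcripts are 2337 to 2368 bases long, and the form named HOTAIR-N was not matched to any of them. NR_047517 took most of the reads, with 475 ± 57.3 counts (SD, n = 3) against 165 ± 2.5 (SD, n = 3), and its log2 fold change was -1.51 (SE 0.12, edgeR quasi-likelihood adjusted p = 0.00044). NR_047518 had a log2 fold change of -1.65 (SE 0.55) that did not pass the test (edgeR quasi-likelihood adjusted p = 0.073), and NR_003716 was too low to be tested, at 11 ± 11 and 5.42 ± 4.73 counts (SD, n = 3).

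Most expressed genes differed between the siRNAs, and interferon-stimulated genes led the rises while genes of cell division and estrogen receptor targets led the falls among the gene groups. The largest rises among genes with an average log2 CPM of at least 0 included APOL3, an interferon-inducible apolipoprotein L, at 42.7-fold from only 0.18 ± 0.0957 CPM (SD, n = 3), IFI44L at 31.4-fold, the antiviral ubiquitin ligase TRIM22 at 26.7-fold and IFIT3, which takes part in the sensing of viral RNA, at 20.6-fold. Genes without a known link to interferon also stood among them, such as SYP, a synaptic vesicle protein, which rose 30.3-fold from 0.919 ± 0.18 to 28 ± 1.64 CPM (SD, n = 3). ANKRD1, a target of YAP, rose 20.5-fold, the proteoglycan gene LUM 19.4-fold and the basal keratin gene KRT17 18-fold, and RTP4, TMEM145, GBP1 and STX19 completed the 12 largest rises. ANKRD1, LUM, KRT17, RTP4 and TMEM145 also started low, at 0.107 to 0.25 CPM on average with the control siRNA. They reached 2.07 to 4.92 CPM with the HOTAIR-N siRNA. Among the 12 largest falls, of which the largest is not printed here, were the leptin receptor gene LEPR to 5.38% of control, the cadherin gene FAT4 to 6.3% and the chemokine receptor gene CXCR4 to 7.04%. ARL6IP1, which shapes the endoplasmic reticulum, fell from the highest level among these, 930 ± 64 CPM, to 98 ± 9.02 CPM (SD, n = 3), and LRRN3, KCNQ5, MBD5, NXPH3, ANKFN1, STOX1 and SLC24A3 fell to between 7.12% and 10.8% of control.

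Of 14919 genes tested, 10605 (71.1%) changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5407 higher and 5198 lower after the HOTAIR-N siRNA. Many of these changes were small. In all, 5732 changed genes differed by less than 1.5-fold, 1330 were higher and 1021 lower by at least 2-fold, and 340 were higher and 149 lower by at least 4-fold. The 3 libraries of one group lay wholly above or below the 3 of the other for 10948 genes (73.4%), where chance alone gives 10%. The first principal component held 85.6% of the variance and separated the groups. Pearson's r across genes was at least 0.995 within a group and at most 0.961 between groups. Control siRNA replicate 2 and HOTAIR-N siRNA replicate 3 differed from the other libraries of their groups in a shared way (r = 0.72 across 8720 genes, which are not independent replicates). Without these libraries 11130 genes changed, 5526 higher and 5604 lower. The 7-mer GACCAAT was picked from these same fold changes, as the one that went with the lowest. Its excess among lower genes thus follows in part from that choice. It was found in the 3′ UTRs of 5.1% of the genes with an annotated one, and of 29 of 128 (22.7%) that were lower by at least 4-fold. Among genes named here whose 3′ UTR could be matched, IFI44L, CXCR4, ARL6IP1, PRLR, EGFR, PPIB, PHF19, SLBP, DTL, PFKFB3, DUSP4, TSNAX, RPL13A and ATP5MG carry it.

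**Figure D1:**
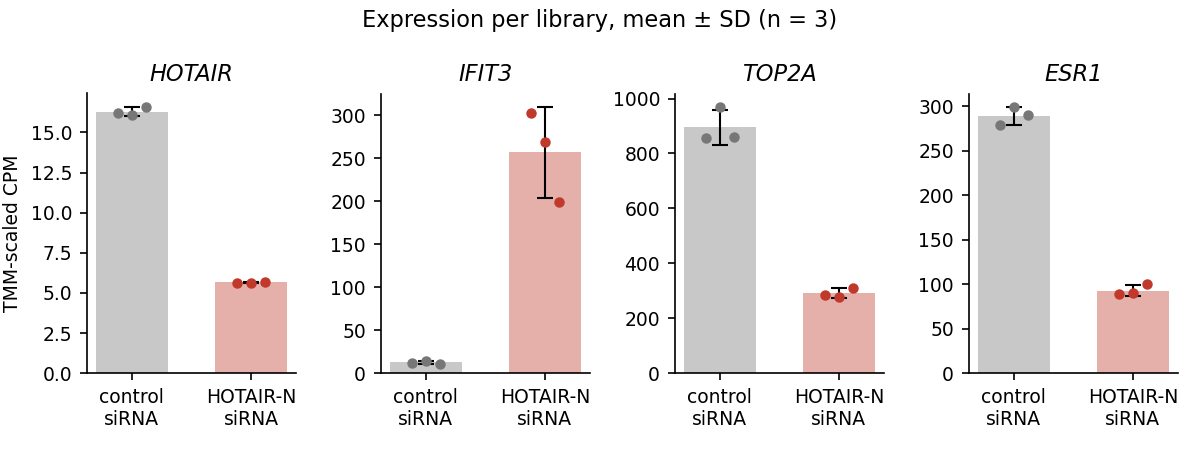
TMM-scaled CPM of HOTAIR, IFIT3, TOP2A and ESR1 in each library of the control siRNA (grey) and the HOTAIR-N siRNA (red). Points are libraries, bars are means and error bars are 1 SD (n = 3); the libraries of the groups do not overlap for any of the 4 genes, and HOTAIR lies at 34.7% of its control level.

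All 54 interferon-stimulated genes were tested and all 54 rose, as they did when adjusted over the list alone. Their median log2 fold change was 2.11. IFIT3 rose from 12.5 ± 1.98 to 257 ± 53.1 CPM and IFIT2 from 6.95 ± 1.01 to 122 ± 18.6 CPM (SD, n = 3). HOTAIR-N siRNA replicate 3 was the lowest of its group for all 54 genes, by 0.28 on the log2 scale below the group mean on average (IFIT3 at 303, 269 and 199 CPM in replicates 1, 2 and 3), and without it 54 rose as well. GBP1, an interferon-induced GTPase, rose 18.5-fold and SAMD9L, an antiviral factor, 11.4-fold. The smallest rise was that of HERC6 (log2 fold change 0.59). The list was called higher by camera (adjusted p = 1.4e-16), with an adjusted p = 0.47 with an estimated correlation, which was 0.8 for this list. Of 33 tested NF-kappaB target genes, 24 rose, 2 fell and 7 were not called, and 25 rose and 2 fell when adjusted over the list alone. BIRC3, an inhibitor of apoptosis, rose 3.34-fold, the chemokine gene CCL2 4.83-fold, TNFAIP3, a feedback inhibitor of NF-kappaB, 2.77-fold and the ribonuclease gene ZC3H12A 2.72-fold. TNIP1 and IER3 fell (log2 fold changes -0.79 and -0.21). This list was called higher too (camera adjusted p = 4.4e-06, and adjusted p = 0.33 with an estimated correlation).

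Genes of mitosis fell almost without exception. Of 51 tested, 50 fell and 1 rose, with the same counts when adjusted over the list alone and a median log2 fold change of -1.05. CDCA8, a subunit of the chromosomal passenger complex, fell to 22% of control, ANLN, a scaffold of the cytokinetic ring, to 30.5%, TOP2A, which untangles DNA before division, from 896 ± 64.1 to 291 ± 17.9 CPM (SD, n = 3), and the kinesin gene KIF23 to 36.1%. The exception was the phosphatase gene CDC25B (log2 fold change 0.73). Of 49 DNA replication genes, 47 fell and 2, E2F2 and RFC4, rose (log2 fold changes 0.2 and 0.3), again with the same counts when adjusted over the list alone. The helicase subunit gene MCM6 fell to 37.4% of control, GINS1 to 34.8%, DTL to 42.6% and SLBP, which binds the stem-loop of histone mRNA, to 40.9%. The replication-dependent histone genes that could be tested went the other way, with 18 of 22 higher, 1 lower and 3 not called. Adjusted over the list alone, 19 were higher and 1 lower. Of the 52 in the list, 30 were too low to be tested, such as HIST1H4C at a mean of 2.3 counts with the control siRNA and 1 with the HOTAIR-N siRNA. The rise thus covers only the histone genes that these libraries detected, not the list as a whole. HIST2H2BE rose 3.56-fold, HIST1H2BG 3.6-fold and HIST1H1C 3.32-fold, and HIST1H2BK fell to 50.8% of control. Histone genes of the same class have similar coding sequences, so that reads could be split among them, and single values are uncertain. Camera called mitosis (adjusted p = 3.3e-16) and DNA replication (adjusted p = 3.9e-10) lower and the tested histone genes higher (adjusted p = 3e-04). With an estimated correlation none passed, at adjusted p = 0.33, 0.24 and 0.35.

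**Figure D2:**
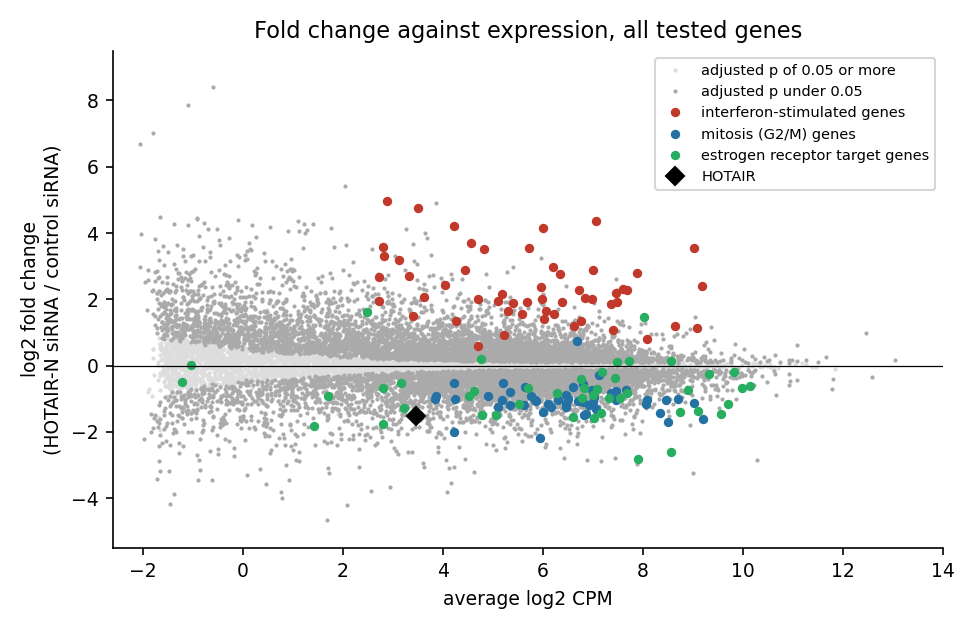
Log2 fold change (HOTAIR-N siRNA over control siRNA) of the 14919 tested genes against average log2 CPM. Light grey points did not pass the test and darker grey points did; all 54 interferon-stimulated genes (red) lie above 0, 50 of 51 mitosis genes (blue) are lower, 37 of 45 estrogen receptor targets (green) are lower, and the diamond is HOTAIR at -1.53.

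The estrogen receptor gene ESR1 fell from 289 ± 9.73 to 93 ± 6.53 CPM (SD, n = 3), and most of the receptor's target genes were lower. Of 45 targets tested, 37 fell, 5 rose and 3 were not called, with 37 lower and 6 higher when adjusted over the list alone and a median log2 fold change of -0.82. OLFM1 fell to 14.2% of control, the chemokine gene CXCL12 to 16.5%, IGFBP4, a binding protein of insulin-like growth factors, to 38.1%, and STC2 to 38.9%. The progesterone receptor gene PGR fell from 1110 ± 43.5 to 406 ± 46.7 CPM (SD, n = 3). TFF1 and HSPB8 rose (log2 fold changes 1.62 and 1.48), as did SIAH2, SLC39A6 and MYC by 0.12 to 0.21 on the log2 scale. The list was called lower (camera adjusted p = 1.6e-08, and adjusted p = 0.24 with an estimated correlation).

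Lists of epithelial and mesenchymal identity held changes both ways and were not called. Of 31 luminal genes, 10 rose and 13 fell by either adjustment (camera adjusted p = 0.64). The prolactin receptor gene PRLR fell from 2180 ± 126 to 305 ± 42.3 CPM (SD, n = 3) and AGR2, a secretory pathway protein, to 46.7% of control, while the receptor kinase gene ERBB3 rose 1.84-fold. Of 19 tested basal and myoepithelial genes, 11 rose and 6 fell by either adjustment (camera adjusted p = 0.12, and adjusted p = 0.6 with an estimated correlation). The smooth muscle actin gene ACTA2 rose 3.81-fold, ANXA1 4.13-fold and DST 2.36-fold, and EGFR fell to 16.4% of control. Of 17 tested mesenchymal genes, 7 rose and 6 fell by either adjustment (camera adjusted p = 0.76). Fibronectin (FN1) fell to 32.4% of control, TAGLN rose 2.18-fold, and THY1 and vimentin (VIM) rose 9.74-fold and 9.03-fold but reached only 1.06 ± 0.0575 and 1.42 ± 0.255 CPM (SD, n = 3). Of 39 integrin, laminin and matrix adhesion genes, 17 rose and 14 fell by either adjustment (camera adjusted p = 0.64). The collagen gene COL12A1 rose 1.98-fold, the integrin gene ITGB6 4.26-fold, the focal adhesion kinase gene PTK2 2.08-fold and LAMB2 2.53-fold.

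Among genes tied to HOTAIR by earlier work, subunits of PRC2 and of LSD1-CoREST were mostly lower. Of 20 tested, 13 fell, 4 rose and 3 were not called by either adjustment (camera adjusted p = 0.01, and adjusted p = 0.33 with an estimated correlation). SUZ12, a core subunit of PRC2, fell from 169 ± 10.8 to 41.1 ± 4.33 CPM (SD, n = 3), EZH2, its methyltransferase, to 39% of control, PHF19, an accessory subunit, to 38.9% and the repressor gene REST to 36.8%. PHF19 carries GACCAAT in its 3′ UTR, and SUZ12, EZH2 and REST do not. Over the 18 members without GACCAAT there the median log2 fold change was -0.37, against -0.43 over all 20. Over the 14 without its last 6 bases it was -0.15. That 7-mer was picked for the low fold changes of its carriers, so part of these shifts follows from the choice. EZH1, EED, RCOR3 and PHF21A rose by 0.17 to 0.41 on the log2 scale. KDM1A, which encodes LSD1, had a log2 fold change of -0.08 (edgeR quasi-likelihood adjusted p = 0.12). Of 14 tested genes linked to HOTAIR in breast cancer, 5 rose and 5 fell by either adjustment (camera adjusted p = 0.87), and the mean log2 fold change of -0.12 had the opposite sign to the median of 0.06. CDKN1A, an inhibitor of cyclin-dependent kinases, rose from 63 ± 2.42 to 130 ± 11.6 CPM (SD, n = 3).

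In the HOXC cluster, where HOTAIR lies between HOXC12 and HOXC11 in the RefSeq annotation of GRCh38.p14, 3 of 12 tested genes rose, 5 fell and 4 were not called by either adjustment (camera adjusted p = 0.48). HOXC4 fell to 33.8% of control, HOXC10 to 77.3% and HOXC13 to 76.8%. HOXC11 rose 1.28-fold from 17 ± 1.09 to 21.8 ± 0.829 CPM (SD, n = 3). It overlaps HOTAIR on the opposite strand, and without the strand setting its value is as uncertain as that of HOTAIR. HOXC12 had 5 counts over the control libraries and 10 over the HOTAIR-N siRNA libraries and was not tested. In the HOXD cluster 3 of 13 genes were expressed highly enough to be tested, too few for camera. By either adjustment 1 rose, the neighbouring gene MTX2 (1.16-fold), and 1 fell, the antisense gene HAGLR (to 38.4% of control), and HOXD11 had a log2 fold change of 0.15 (SE 0.33, edgeR quasi-likelihood adjusted p = 0.72).

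**Figure D3:**
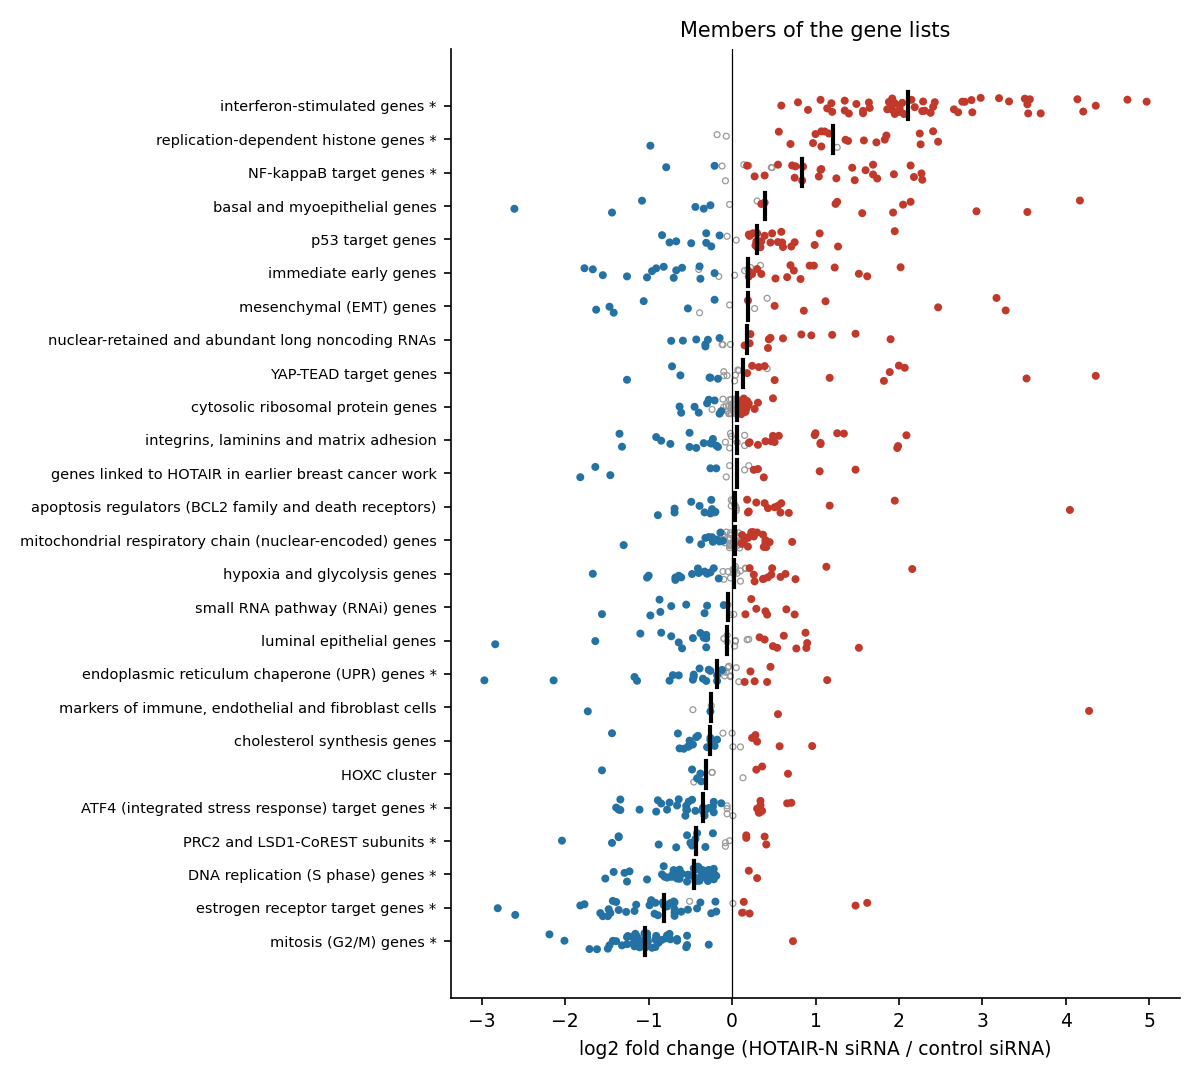
Log2 fold change (HOTAIR-N siRNA over control siRNA) of the members of the 26 tested lists, sorted by the median, drawn as a black bar. Red and blue points are members called higher and lower, open points were not called, and an asterisk marks the 9 lists that camera called; medians run from -1.05 for mitosis to 2.11 for interferon-stimulated genes.

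Lists of stress responses were lower where they were called. Of 40 ATF4 target genes, 28 fell, 8 rose and 4 were not called by either adjustment (camera adjusted p = 0.0012, and adjusted p = 0.33 with an estimated correlation). PHGDH, the entry enzyme of serine synthesis, fell to 38.3% of control, ATF5 to 39.6% and the arginine transporter gene SLC7A1 to 55.6%, while the stress regulators ATF3 and TRIB3 rose (log2 fold changes 0.66 and 0.32). Of 33 endoplasmic reticulum chaperone genes, 18 fell, 6 rose and 9 were not called by either adjustment (camera adjusted p = 0.02, and adjusted p = 0.49 with an estimated correlation). PPIB, a prolyl isomerase, fell from 422 ± 10.2 to 53.7 ± 0.75 CPM (SD, n = 3), OSTC to 22.7% of control, the transcription factor gene XBP1 to 44.5% and SEC61B to 45.3%. Cholesterol synthesis (5 higher and 15 lower of 24, camera adjusted p = 0.071), hypoxia and glycolysis (13 and 15 of 41, adjusted p = 0.87) and immediate early genes (16 and 14 of 37, adjusted p = 0.87) were not called, with the same counts when adjusted over the list alone. Without control siRNA replicate 2 and HOTAIR-N siRNA replicate 3 the cholesterol list was called lower (camera adjusted p = 0.043), and with all libraries it had an adjusted p = 0.33 with an estimated correlation. INSIG1 fell to 36.8% of control and HMGCS1 rose 1.94-fold, FDFT1 and ACAT2 fell to 70% and 63.8%, PFKFB3, PGAM1 and HK1 fell to 31.4%, 50% and 64.4% and EGLN3 rose 4.47-fold. DUSP5, DUSP4 and EGR3 fell to 41.9%, 34.1% and 29.3% of control, and JUN rose 2.35-fold.

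Of 33 p53 target genes, 23 rose and 8 fell by either adjustment, with a camera adjusted p = 0.064, and adjusted p = 0.45 with an estimated correlation. At the preset correlation the list passed the threshold with a filter of 1 CPM in 3 libraries (adjusted p = 0.049), without control siRNA replicate 1 (adjusted p = 0.048), without HOTAIR-N siRNA replicate 3 (adjusted p = 0.049) and without control siRNA replicate 2 and HOTAIR-N siRNA replicate 3 (adjusted p = 0.035). The kinase gene PLK2 rose 2.41-fold, the BH3-only gene PMAIP1 3.87-fold and TP53I3 1.52-fold. Apoptosis regulators (14 higher and 10 lower of 32, camera adjusted p = 0.63) and YAP-TEAD targets (12 and 6 of 26, camera adjusted p = 0.3) were not called, with the same counts when adjusted over the list alone. The initiator caspase gene CASP10 rose 16.6-fold from 0.242 ± 0.137 to 4.03 ± 0.0612 CPM (SD, n = 3) and MCL1 1.42-fold, and survivin (BIRC5) fell to 54% of control. CYR61 rose 4.2-fold and PAWR 3.54-fold, and MYOF fell to 60.7% of control.

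Lists of basic cell functions were not called. Of 79 ribosomal protein genes, 29 rose and 9 fell, or 27 and 9 when adjusted over the list alone (camera adjusted p = 0.33). With library totals as the only scaling 57 rose and 7 fell, and the list was called higher (camera adjusted p = 0.027); with TMM scaling and an estimated correlation its adjusted p = 0.85. RPL19, RPL13A and RPL7A fell to 65.4%, 64.6% and 73% of control and RPL23A rose 1.4-fold, values that processed pseudogenes could affect. Of 58 nuclear-encoded respiratory chain genes, 18 rose and 11 fell, or 16 and 11 when adjusted over the list alone (camera adjusted p = 0.59). COX7A2 fell to 40.7% and ATP5MG to 70.1% of control, and CYCS rose 1.64-fold. Of 19 genes of the small RNA pathway, 7 rose and 9 fell by either adjustment (camera adjusted p = 0.44). TSNAX fell to 34% of control, and DICER1, XPO5 and TNRC6C to 54.8%, 55.1% and 50.8%. Of 22 abundant long noncoding RNAs, 12 rose and 7 fell by either adjustment (camera adjusted p = 0.35). NEAT1, the scaffold of paraspeckles, rose from 277 ± 2.91 to 773 ± 40.8 CPM (SD, n = 3), CYTOR 3.74-fold, PVT1 2.3-fold and SNHG3 1.93-fold. Of 24 markers of immune, endothelial and fibroblast cells 6 were expressed highly enough to be tested, of which LUM and CD68 rose and COL3A1 and COL1A1 fell by either adjustment (camera adjusted p = 0.94), with a median of -0.25 and a mean of 0.35. COL1A1 lost its call with library totals as the only scaling (log2 fold change -0.16, edgeR quasi-likelihood adjusted p = 0.0862).

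At the level of annotated transcripts, 10327 of 32285 tested changed, 4967 higher and 5360 lower (edgeR quasi-likelihood test, adjusted p under 0.05), and 479 of 7465 genes changed the shares of their transcripts. In TPM1, which encodes tropomyosin, the share of NM_001018006 fell from 83.9% ± 0.433 to 54.6% ± 2.17 (SD, n = 3) and that of NM_000366 rose from 5.42% ± 0.328 to 33.5% ± 1.84 (SD, n = 3). In CTNND1, which encodes the cadherin partner p120-catenin, NM_001085468 fell from 41.9% ± 1.75 to 21.5% ± 2.07 (SD, n = 3) and NM_001085464 rose from 25.2% ± 1.29 to 33.9% ± 2.54 (SD, n = 3). In ASPH, an endoplasmic reticulum hydroxylase, the long NM_004318 fell from 35.7% ± 0.35 to 14.1% ± 0.505 (SD, n = 3) and NM_032466 rose from 32.1% ± 1.61 to 57% ± 1.58 (SD, n = 3). In CELF1, an RNA-binding splicing regulator, NM_001172640 fell from 22.9% ± 2.58 to 5.28% ± 1.35 (SD, n = 3). The fifth gene, C6orf48, is listed with several copies of each transcript, between which reads cannot be told apart, so its call is uncertain. The usage test made too many calls on simulated counts, where 52 of 155 called genes had no planted switch. A test of each transcript's share of its gene, chosen after the data were examined, called 951 genes, 395 of them among the 479, with C6orf48 not among its calls (limma adjusted p = 0.17).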

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

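The alternatives without control siRNA replicate 2 and HOTAIR-N siRNA replicate 3 together, without genes that carry the leading 7-mer, and the share test of transcript usage were chosen after the data were examined; the others were planned. HOTAIR kept its call in the 15 alternative settings in which single genes were tested (log2 fold change -1.56 to -1.43), and 121 of 123 other genes chosen for naming kept call and direction in those of the 15 whose filter kept the gene; the exceptions were COL1A1 and HOXD11, which was not called and went from 0.15 to -0.04 without control siRNA replicate 1 and 0.28 without HOTAIR-N siRNA replicate 1. Tested against a 1.2-fold change, 6876 genes were called, 3564 higher and 3312 lower; at least 2-fold changes numbered 2351, 1330 and 1021. Both settings ask for larger changes. With each library left out the counts ran from 9906 to 10727 genes changed, 5015 to 5442 higher, 4866 to 5285 lower, -1.54 to -1.52 for HOTAIR, 9 to 10 lists, 8000 to 9237 transcripts and 359 to 408 usage genes. Library totals alone moved the median log2 fold change of all genes from 0.018 to 0.116 and the share of changed genes that were higher from 51% to 60.3%. Replicate numbers do not pair the libraries (correlations of deviations -0.04, -0.21 and -0.12, none correlating best with its own number); the replicate block left 10010 changed genes, 6219 transcripts and 276 usage genes, with fewer residual degrees of freedom. The share test called 951 usage genes. Of the lists, 0 were called by camera with an estimated correlation (3 at an unadjusted p under 0.05) and 21 by fry, which asks another question. Without genes that carry the 7-mer, 10 lists were called, basal and myoepithelial genes among them; as the 7-mer was picked for the low fold changes of its carriers, this setting moves lists upward by choice. Camera's direction, as mean z of members minus other genes, turned only for lists called in neither setting; the cause was not tested. The cell type markers went to -0.127 with library totals, -0.0441 with the block, -0.352 without both libraries, and -0.558 to -0.0431 with 1 library left out, but 0.22 without control siRNA replicate 1; immediate early genes to -0.101 with library totals and -0.00107 without control siRNA replicate 3, but 0.254 without both libraries; genes linked to HOTAIR to 0.000242 and hypoxia genes to 0.0217 without genes that carry the 7-mer. About 32 to 37 counts stand for 1 CPM, which limits calls near the filter.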

Other observations

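Gene groups outside the fixed lists were examined with 5 lists. These were chosen after the data were seen, when related genes had been found to change, so only counts of called genes are given and no test of a list. Of 15 tested genes of MHC class I antigen presentation, all 15 rose, with a median log2 fold change of 1.16. HLA-B rose from 315 ± 11 to 674 ± 86.2 CPM, the class I transactivator gene NLRC5 from 3.2 ± 0.363 to 19 ± 3.97 CPM and the peptide trimming gene ERAP1 from 31.6 ± 1.23 to 101 ± 2.76 CPM (SD, n = 3). HLA genes share reads with one another, so that single values are uncertain. Of 7 guanylate-binding protein and APOL genes besides GBP1, all 7 rose, with APOL1 up 12.7-fold and GBP2 6.78-fold. Of 27 core splicing factor genes 22 fell and 2 rose (median log2 fold change -0.44). Of 28 lysosomal genes 13 rose and 7 fell, and of 13 genes of prolactin, progesterone and androgen signalling 6 rose and 6 fell.

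Transcripts of the interferon genes themselves were few. Over the 3 libraries of a group, IFNB1 had 2 counts with the control siRNA and 20 with the HOTAIR-N siRNA, IFNL1 15 and 40, and IFNL3 3 and 17.

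In what follows, the tests of the 7-mer scan in 3′ UTRs, of coding sequence sites and of mitosis genes without the 7-mer were planned before their results were seen; the tests of base composition, of the rising 7-mer, of genes without the site, of scaling, of leukocyte genes and of IFNB1, and the counts over other splits, were chosen after the results were seen.

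Among 15713 7-mers, the one that went with the lowest fold changes was GACCAAT, with z = -11.53 and a shift of -0.37 (SE 0.032) over 659 genes. Of these 659 genes, 58.9% were called lower against 36.1% of other genes, and 164 were called higher. GACCAAT is carried by genes that fell, such as PPIB, ARL6IP1, CXCR4, EGFR and PRLR, and by IFI44L, which rose. The lowest z of other 7-mers of the same bases was -4.23 once those that share 6 bases in a row with it are left out (TGACCAA, one of these, had -6.03), which argues against its base composition alone; shuffled fold changes reached 5.53, and the unrelated TTTTTTA, at -7.54 over 5477 genes, went beyond that too. The shift was -0.58 with the 7-mer followed by A and -0.38 with the 7-mer not followed by A. Without the full 7-mer it was -0.28 with its last 6 bases followed by A and -0.14 with those 6 bases alone. The 7-mer occurs in the annotated HOTAIR-201 (13.8% of all 7-mers occur in at least 1 of the HOTAIR transcripts), but HOTAIR-N was not matched to an annotated transcript. Seed matches of the HOTAIR-N siRNA may account for part of the falls, which cannot be checked without its sequence. Of 4785 lower genes with a 3′ UTR, 3454 lack those 6 bases, so sites of this 7-mer there cannot account directly for their falls. That count does not test the explanation for the other lower genes, since most of the 12849 genes lack the 6 bases too (carriers by site type: 197, 462, 673 and 1291). A motif that acts anywhere in the mRNA stays open, since genes with the 7-mer in the coding sequence only had a shift of -0.24 against -0.44 for those with it in the 3′ UTR only. The length and GC content of the coding sequence were not in the model, so the shift of -0.24 may not be due to the 7-mer. Among rising genes GAATATA reached z = 11.33 and also occurs in HOTAIR-201, and without the sequence of the control siRNA its seed matches cannot be told apart from other origins.

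The fall of mitosis genes was not carried by sites of the leading 7-mer in their own 3′ UTRs. The 49 mitosis genes without it had a median log2 fold change of -1.04, where all 51 had -1.05. With library totals as the only scaling 50 were called lower, which argues against scaling between libraries. An effect of HOTAIR loss, or one that passes through other genes that fell, such as ESR1, stays open and was not tested.

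The rise of the 54 interferon-stimulated genes was compared with the level of leukocyte genes. PTPRC, CD3E, CD14, LYZ, CD4 and MS4A1 together reached at most 0.44 CPM in a HOTAIR-N siRNA library and 0.39 CPM in a control siRNA library. These low sums argue against immune cells that express these genes. CD68, from the fixed list of immune, endothelial and fibroblast markers, did rise, from 2.33 ± 0.114 to 3.43 ± 0.394 CPM (SD, n = 3). The cause of the CD68 rise was not tested. With library totals as the only scaling 54 interferon-stimulated genes were called higher, which argues against scaling. Sensing of the transfected RNA may account for the rise of the interferon-stimulated genes, as may the loss of HOTAIR. IFNB1 had 20 counts over the HOTAIR-N siRNA libraries, which goes with either, and with 1 siRNA in each group these explanations cannot be told apart.

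The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split with as many as 10605 genes changed, 5407 higher, 5198 lower, 10327 transcripts and 479 usage genes. The highest of the other 9 splits had 0 genes and 0 transcripts by edgeR's adjusted p (20 to 145 genes and 348 to 531 transcripts at an unadjusted p under 0.05) and 24 usage genes. For the gene lists, 3 of the 10 splits called at least 9, the real one included, the highest of the others was 9 and the lowest 5. Each of these other splits exchanges 1 library per group and so still holds part of the difference between the siRNAs. The exchanged library also widens the spread within each group, which lowers the number of genes and transcripts called. The counts of the other splits are therefore not a chance level.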
